A study of Pseudomonas aeruginosa with 8 samples.

How the data were processed

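RNA sequencing had been done on Pseudomonas aeruginosa PAO1, a laboratory reference strain, in 4 groups of 2 biological replicates (8 libraries). Cultures in CAMHB, a cation-adjusted Mueller-Hinton broth, were treated from an OD600 of 1 for 30 min at 37 °C. One group was an untreated control. The others received bismuth subsalicylate (BSS, a bismuth salt used as a drug) at 16 µM, eravacycline (a fluorocycline of the tetracycline class, which binds the ribosome) at 0.5 µM, or both at these doses, called the combination here. Per the labels, cells were broken with glass beads, total RNA was extracted with TRIzol, and libraries followed a standard BGI protocol for Illumina sequencing. No batch, day or pairing of replicates was stated. The name of the table deposited for BSS replicate 1 carries a number that matches no dose in the labels, and the dose in the labels was used, so the dose of that library is less certain than the others.

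The deposited tables hold raw read counts per annotated gene, 1 table per library, with 5677 genes in each. Per the labels, the authors aligned the reads with Bowtie2 (version not given), and the positions in the tables refer to the PAO1 chromosome. The counting program, its strand setting, its treatment of reads with several matches and any removal of ribosomal RNA (rRNA) are not given in the sources used here, so values of overlapping genes and of near-identical copies such as tufA and tufB are uncertain. The genes comprised 5514 protein-coding genes, 13 rRNA genes, 63 transfer RNA (tRNA) genes and 28 non-coding RNA genes. Of their identifiers, 5635 matched the RefSeq gene table, 5616 of them with the same start, and 42 did not match. Symbols for 1766 genes came from that table and symbols for 86 listed genes from the fixed lists. All positions below are counted from 1 on the PAO1 reference chromosome named in the count tables.

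Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which kept 5647 genes and removed 30. Library sizes were scaled with TMM factors. A model with 1 mean per group was fitted to all 8 libraries, which left 4 residual degrees of freedom, with quasi-likelihood fits (glmQLFit with legacy set to FALSE, since the function's default in this version is TRUE) and F tests (two-sided). Benjamini-Hochberg adjustment covered all genes tested in a comparison, and a gene was called changed at an adjusted p under 0.05. The 6 comparisons were BSS, eravacycline and the combination each against control, the combination against eravacycline and against BSS, and the interaction of both drugs, which is the BSS effect with eravacycline minus the BSS effect without it, on the log2 scale. Standard errors (SE) of log2 fold changes were taken as the absolute value divided by the square root of F and are approximate. Levels are TMM-normalised counts scaled to a library of 1e6 (CPM), given as mean ± SD with n = 2 per group.

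For a test on simulated data, counts were drawn from the fitted means and spread with 200 genes changed by a known fold in a comparison. The model recovered 72% to 94% of genes changed 2-fold and 20% to 34% of genes changed 1.5-fold, depending on the comparison. Between 3.11% and 6.17% of its calls were false. The groups compared shared the same mean apart from those 200 genes, and each gene had 1 spread in all groups. The simulation therefore does not show how the model performs where most genes change or where groups differ in spread.

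There were 25 gene lists, with 542 genes present in the files. They were fixed from textbook knowledge, as were the comparisons, the tests and the rule for naming genes, before the data were examined, and 1 further listed gene was dropped because the RefSeq table gives its identifier to another gene. Lists were tested in limma 3.58.1 with camera, which compares a list with all other genes, on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 25 lists of a comparison. They were tested again with a correlation estimated from the data, and with fry, which asks whether a list's genes move, on balance, in 1 direction. Members past the gene test were counted over all genes tested and adjusted over the list alone.

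Genes were named by a rule with 3 parts. The first took, for each pairwise comparison, up to 6 genes with the largest rise and 6 with the largest fall among called genes with a symbol, a mean of at least 10 CPM over all libraries and no overlap between replicates of the groups compared, rRNA and tRNA genes excluded. For the interaction it took 4 in each direction. The second took up to 4 called members per list with the largest change, or the 2 most highly expressed members where none was called. The third took pvdS, fpvA, pvdA, fptA, pchA, hasAp, phuR, sodM, fumC1, bfd, katA, mexX, mexY, armZ, mexA, mexB, groEL, rpsA and recA whatever their values. Genes outside the rule are said to have been chosen after their values were seen.

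Alternatives were RLE size factors, library sizes without TMM factors, no filter, a filter of 10 CPM in at least 2 libraries, DESeq2 1.42.0, the legacy quasi-likelihood fit, only the groups compared in the fit, the replicate number as a block, rRNA and tRNA genes removed before library sizes, and each library left out in turn. For the lists they were the estimated correlation, a prior count of 0.5, the block and the left-out libraries. Ranges of a list's adjusted p cover the last 10 of these, and the value with the estimated correlation is given apart from them. One setting was chosen after the data were seen, with rRNA and tRNA genes removed and BSS replicate 2 left out. Where a left-out library leaves a group with 1, that library is assumed to vary like the other groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the results reported.

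Total counts per library ranged from 9.08 M to 30.68 M (M, 1e6 counts) and protein-coding counts from 2.20 M to 12.33 M. Intervals for the share of counts on rRNA genes are exact Clopper-Pearson 95% intervals and cover counting error only.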

Results

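The data were gene counts from 8 libraries of Pseudomonas aeruginosa PAO1, with 2 each from control, BSS, eravacycline and combination cultures sampled after 30 min. Total counts in replicates 1 and 2 were 11.97 M and 10.69 M in control, 13.25 and 30.68 M with BSS, 17.99 and 11.30 M with eravacycline, and 21.50 and 9.08 M with the combination. The share of counts on rRNA genes was 9.36% (95% interval 9.345% to 9.378%) and 7.88% (7.865% to 7.897%) in the control libraries. It was 3.89% (3.882% to 3.903%) in BSS replicate 1 and 92.49% (92.48% to 92.50%) in BSS replicate 2. With eravacycline it was 59.15% (59.13% to 59.17%) and 52.48% (52.45% to 52.51%), and with the combination 52.72% (52.70% to 52.74%) and 25.28% (25.25% to 25.31%). BSS replicate 2 therefore held 2.20 M protein-coding counts, against 5.31 to 12.33 M in the other 7 libraries.

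**Figure D1:**
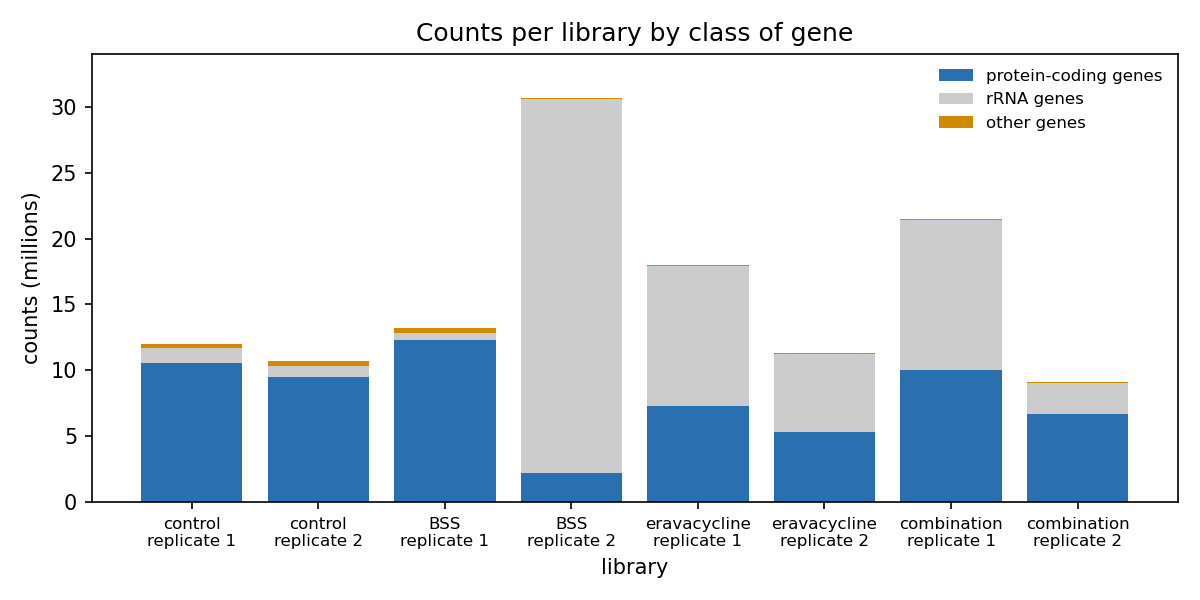
Stacked bars give the counts of each library in M, split into protein-coding, rRNA and other genes, for the 2 replicates of each group. BSS replicate 2 has the highest total, 30.68 M, of which 92.5% lies on rRNA genes.

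Replicates of a group correlated across genes at r = 0.995 in control, 0.980 with BSS, 0.996 with eravacycline and 0.997 with the combination (log2 CPM, genes are not independent replicates). The first principal component held 88.9% of the variance and separated the 4 libraries with eravacycline (70.9 to 76.3) from the 4 without it (-75.8 to -70.1). The second held 5.83% and placed the control libraries at -22.7 and -24.6 and the BSS libraries at 11.8 (replicate 1) and 37.2 (replicate 2), so the 2 BSS libraries lay further apart than the replicates of any other group. Non-coding RNA made up 2.27% ± 0.487 (SD, n = 2) of the counts outside rRNA in control and 2.95% ± 0.877 with BSS, against 0.389% ± 0.00290 with eravacycline and 0.250% ± 0.0144 with the combination.

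The comparison of BSS with control asks what the bismuth drug changed on its own. The gene inaA (PA4378, 4909401 to 4910105, minus strand) rose 54.4-fold, from 16.8 ± 1.04 to 915 ± 157 CPM (n = 2 per group, log2 fold change 5.77 ± 0.17 SE, adjusted p = 9.51e-08). All 3 genes of the arsenic resistance operon, which encodes the repressor ArsR, the efflux pump ArsB and the arsenate reductase ArsC, rose. The gain was 51.0-fold for arsC (PA2279, 2508293 to 2508763, plus strand), from 3.13 ± 0.230 to 160 ± 1.02 CPM. It was 25.4-fold for arsR (2506614 to 2506964) and 22.5-fold for arsB (2506978 to 2508261). The phosphatase gene tpbA (PA3885, 4350834 to 4351490, plus strand), linked to biofilm formation, rose 27.4-fold, from 1.27 ± 0.0230 to 34.9 ± 8.61 CPM. The largest falls by the naming rule were in narK1, a nitrate transporter (14.9-fold, from 111 ± 5.08 to 7.44 ± 1.68 CPM), and the efflux genes mexJ (6.39-fold) and mexK (4.78-fold). Others were in the ferripyoverdine receptor gene fpvA (5.53-fold, from 123 ± 14.8 to 22.2 ± 0.632 CPM) and the porin genes oprF (4.85-fold) and oprD (4.64-fold).

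Over all 5647 genes tested, 1507 (26.7%) changed with BSS, 649 higher and 858 lower. Of these, 259 and 222 changed by at least 2-fold. Leaving out 1 library gave 963 genes without control replicate 1, 843 without control replicate 2, 2501 without BSS replicate 1 and 1587 without BSS replicate 2. The last 2 counts hold 1420 and 1251 of the 1507. Without BSS replicate 2, the sign of the log2 fold change differed for 4 of the 1507. The fit of the control and BSS groups alone gave 868 genes. With library sizes only, edgeR called 0 genes (33 at an unadjusted p under 0.05, against 1213 called by DESeq2 with its own size factors), and the median log2 fold change of all genes moved from -0.02 to -0.50. Directions below are therefore relative to TMM scaling.

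Of the 25 gene lists, 5 were higher with BSS relative to all other genes. The cationic peptide and PmrAB/PhoPQ response, controlled by sensors of cationic peptides and magnesium, had 11 of 15 members higher (11 adjusted over the list alone) at a median log2 fold change of 1.59 (camera adjusted p = 1.3e-08, and adjusted p = 0.145 with an estimated correlation). Its PA4774, ahead of pmrAB, rose 5.21-fold, from 37.5 ± 1.43 to 195 ± 12.3 CPM, and pmrB rose 3.46-fold. Multidrug efflux had 11 of 32 members higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.27 with an estimated correlation), at a median of 0.23 that was -0.33 with library sizes only, against -0.50 for all genes. The pump genes mexF (3.16-fold), mexE (3.11-fold), mexY (2.79-fold) and mexX (2.15-fold) rose while mexJ and mexK fell, and 7 members were lower without BSS replicate 1. Iron-sulfur cluster assembly had 4 of 8 members higher (4 adjusted over the list alone), at a median of 0.44 (camera adjusted p = 0.00374, and adjusted p = 0.27 with an estimated correlation). Among them were the regulator gene iscR (1.89-fold) and fdx2 (1.71-fold). Alginate had 1 of 12 members higher, algA (1.69-fold, 1 adjusted over the list alone, camera adjusted p = 0.00295, and adjusted p = 0.145 with an estimated correlation), at a median of 0.49 that was -0.03 with library sizes only. There were 2 higher without BSS replicate 2 or either eravacycline replicate. Zinc limitation had 5 of 28 members higher (4 adjusted over the list alone, camera adjusted p = 0.0285, and adjusted p = 0.19 with an estimated correlation), at a median of 0.24 that was -0.21 with library sizes only, and PA2437 rose 3.87-fold. Without BSS replicate 1 the adjusted p was 0.159 for iron-sulfur cluster assembly (6.88e-05 to 0.159 over the 10 alternatives other than the estimated correlation, as in all such ranges here), 0.0804 for multidrug efflux (0.00684 to 0.0804) and 0.159 for zinc limitation (0.0104 to 0.159). For zinc limitation it was also 0.0809 without control replicate 1. Without BSS replicate 2, which had 92.5% of its counts on rRNA, 12 members of the PmrAB/PhoPQ list, 13 of multidrug efflux and 8 of iron-sulfur cluster assembly were higher. Zinc limitation had 2 higher without control replicate 2.

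Another 10 lists were lower with BSS. Ribosomal proteins had 45 of 53 members lower (48 lower and 1 higher adjusted over the list alone), at a median log2 fold change of -1.16 (camera adjusted p = 1.09e-16, and adjusted p = 0.27 with an estimated correlation). The gene rplJ fell 3.67-fold, from 3358 ± 628 to 916 ± 365 CPM, rplL 3.58-fold and rplR 3.55-fold. Translation factors and ribosome assembly had 11 of 17 members lower (15 adjusted over the list alone) at a median of -0.76 (camera adjusted p = 9.62e-06, and adjusted p = 0.27 with an estimated correlation). The elongation factor gene tsf fell 2.61-fold. ATP synthase had 8 of 9 members lower (8 adjusted over the list alone) at a median of -1.18 (camera adjusted p = 0.000116, and adjusted p = 0.145 with an estimated correlation). Its atpB fell 2.45-fold. Heat shock had 7 of 15 members lower (9 adjusted over the list alone) at a median of -0.52 (camera adjusted p = 0.000753, and adjusted p = 0.35 with an estimated correlation). The cochaperone gene grpE fell 2.00-fold. Without BSS replicate 2 the ribosomal protein list had 51 members lower at a median of -0.88, translation factors 12, ATP synthase 8 and heat shock 6. Translation factors had 4 without control replicate 2 and 14 without BSS replicate 1. ATP synthase had 5 without control replicate 2, and heat shock had 4 without control replicate 1 and 13 without BSS replicate 1.

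The remaining 6 of these lists follow. Pyochelin, a siderophore system, had 13 of 14 members lower (13 adjusted over the list alone) at a median of -1.06 (camera adjusted p = 2.1e-07, and adjusted p = 0.19 with an estimated correlation). The receptor gene fptA fell 2.62-fold (from 314 ± 11.1 to 120 ± 10.8 CPM) and pchD 2.47-fold. Pyoverdine, the second siderophore system, had 6 of 19 members lower (6 adjusted over the list alone) at a median of -0.22 (camera adjusted p = 0.0369, and adjusted p = 0.27 with an estimated correlation). Among them were fpvA and pvdA (2.75-fold), while its sigma factor gene pvdS had a log2 fold change of 0.02 (adjusted p = 0.964). Its call ended without control replicate 2 (adjusted p = 0.134) and without BSS replicate 2 (0.123, range 0.0129 to 0.134 over 10 alternatives), and its count ranged down to 2. Type III secretion, which injects toxins into host cells, had 26 of 38 members lower (30 lower and 1 higher adjusted over the list alone) at a median of -0.76 (camera adjusted p = 2.3e-09, and adjusted p = 0.145 with an estimated correlation). The needle tip gene pcrV fell 2.38-fold. Quorum sensing and secreted virulence factors had 15 of 26 members lower and 1 higher (17 and 1 adjusted over the list alone) at a median of -0.64 (camera adjusted p = 6.43e-06, and adjusted p = 0.27 with an estimated correlation). Falls were in the anthranilate synthase genes phnA (4.49-fold) and phnB (3.72-fold) and the quinolone signal genes pqsE (3.53-fold) and pqsA (3.23-fold). Sulfur assimilation and sulfonate use had 12 of 22 members lower (12 lower and 1 higher adjusted over the list alone) at a median of -0.43 (camera adjusted p = 0.0012, and adjusted p = 0.145 with an estimated correlation). The sulfate adenylyltransferase gene cysD fell 3.05-fold. Flagella and chemotaxis had 5 of 43 members lower (4 adjusted over the list alone) at a median of -0.21 (camera adjusted p = 0.0123, and adjusted p = 0.35 with an estimated correlation). Its count was 0 in edgeR without control replicate 2 and 16 without BSS replicate 1. Without BSS replicate 2, 13 pyochelin, 3 pyoverdine, 27 type III secretion, 14 quorum sensing, 11 sulfur and 8 flagella members were lower. Pyochelin had 8 without control replicate 1.

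The other 10 lists did not pass the camera test with BSS. Copper, zinc and cadmium efflux had 5 of 13 members higher (5 adjusted over the list alone, adjusted p = 0.052) at a median of 0.29 that was -0.11 with library sizes only. Among them were czcR (2.87-fold) and the metal transporter gene PA3690 (2.82-fold, from 48.5 ± 5.58 to 137 ± 4.71 CPM). It passed without control replicate 2 (adjusted p = 0.0248) and without BSS replicate 2 (0.0123, range 0.0123 to 0.407 over 10 alternatives), with 3 members called in each. The list of other iron uptake and Fur-repressed genes had 5 of 22 members lower (5 adjusted over the list alone, adjusted p = 0.052). Among these were the receptor genes fecA (2.83-fold) and piuA (2.13-fold) and the ferrous iron transporter gene feoB (1.86-fold). It passed without control replicate 1 (0.0468), BSS replicate 2 (0.00828, with 8 members), combination replicate 1 (0.0423) or combination replicate 2 (0.0421), over a range of 0.00828 to 0.407. Denitrification and arginine fermentation had 4 of 25 members higher and 7 lower (4 and 8 adjusted over the list alone, adjusted p = 0.519), with a median of 0.05, which was -0.41 with library sizes only, and a mean of -0.29. Its narK2 (4.40-fold) and the nitrite reductase gene nirS (2.55-fold) fell. None of its members was higher without control replicate 2. The aerobic respiratory chain had 7 of 36 members higher and 10 lower (7 and 11 adjusted over the list alone, adjusted p = 0.557), with a median of -0.21 and a mean of 0.16. The lower count was 18 without BSS replicate 1. Its cyoA, cyoB and cyoC, of the cytochrome bo3 oxidase, rose 9.29-fold, 9.87-fold and 10.4-fold. Oxidative stress had 2 of 13 members higher (2 adjusted over the list alone, adjusted p = 0.127), tpx (2.09-fold) being 1 of them, at a median of 0.16 that was -0.47 with library sizes only. Without BSS replicate 1, 5 were higher. H1 type VI secretion (adjusted p = 0.174, median 0.08, or -0.34 with library sizes only), SOS response and pyocins (adjusted p = 0.748, median -0.05) and the Pf1 prophage (adjusted p = 0.78, median -0.02) had 1 of 15 members higher, 2 of 39 lower and 1 of 12 higher, of which 0 passed in edgeR when adjusted over the list alone. Without BSS replicate 1 the type VI list had 3 higher and 2 lower and Pf1 had 3 higher and 3 lower, and without either control replicate edgeR called 0 of both higher. For SOS response and pyocins 10 were lower and 4 higher without BSS replicate 1. Heme uptake (adjusted p = 0.557, median -0.04) and anthranilate and catechol degradation (adjusted p = 0.748, median 0.14, or -0.53 with library sizes only) had 0 of 10 and 0 of 6 members called by edgeR and by DESeq2, with 1 and 0 at an unadjusted p under 0.05. By fry, 5 of these 10 lists passed: other iron uptake (adjusted p = 0.011, lower), oxidative stress (0.00498, higher), denitrification and arginine fermentation (0.0026, lower), H1 type VI secretion (0.0447, higher) and copper, zinc and cadmium efflux (0.00895, higher).

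**Figure D2:**
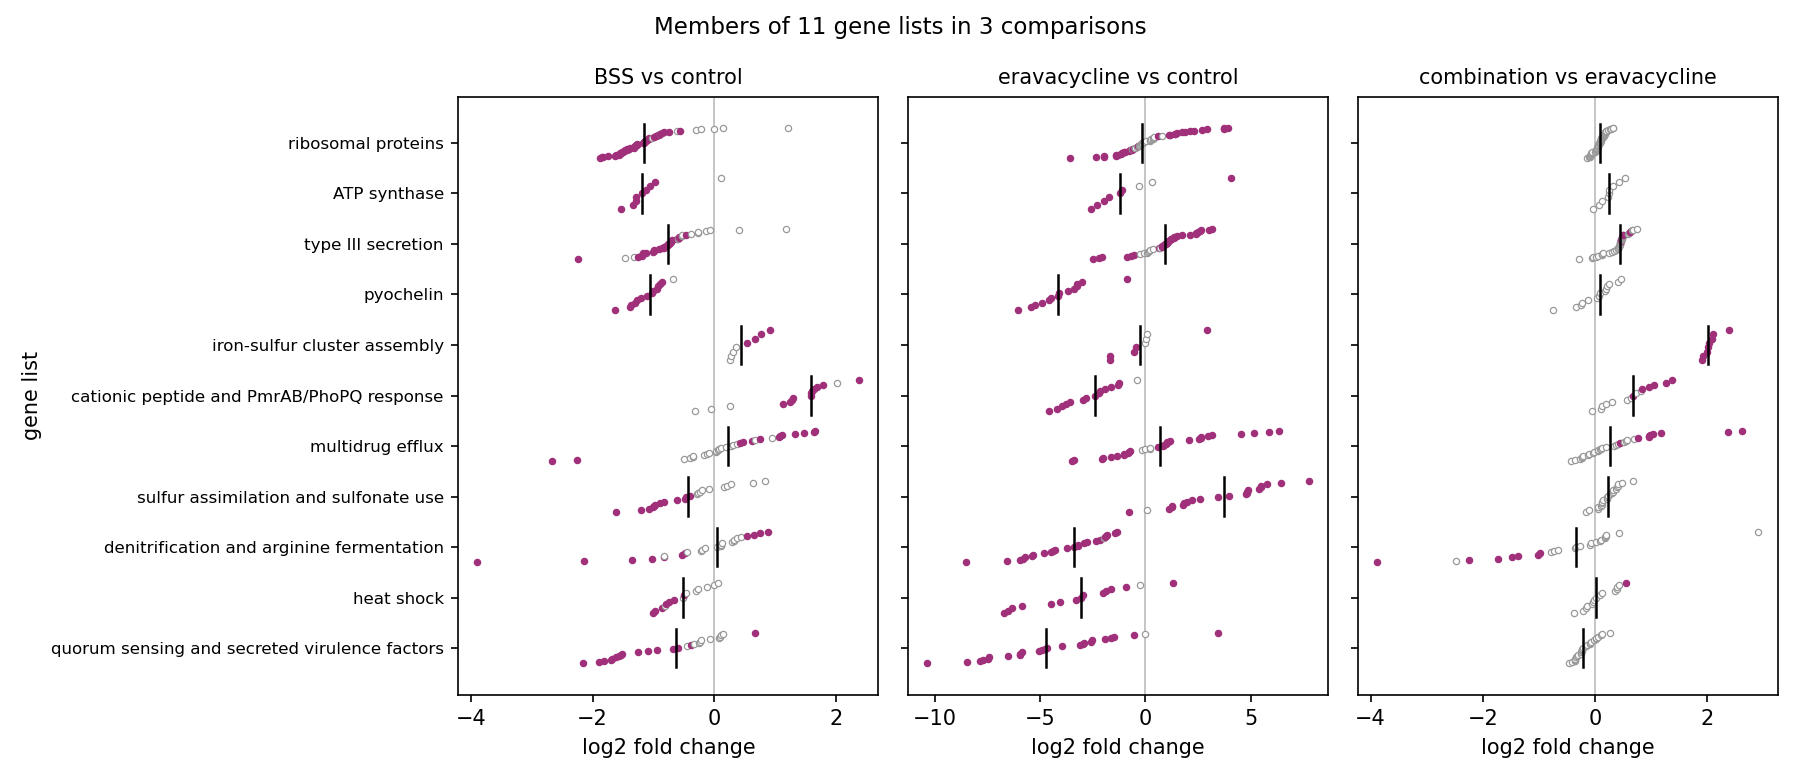
Points give the log2 fold change of each member of 11 gene lists in 3 comparisons, filled where the adjusted p is under 0.05, and vertical bars give list medians. With BSS the ribosomal proteins lie lower than control (median -1.16), and the iron-sulfur cluster genes are higher in the combination than with eravacycline (median 2.02).

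The comparison of eravacycline with control asks how cells responded to a ribosome inhibitor. The multidrug efflux genes mexX (PA2019, 2211322 to 2212512, minus strand) and mexY rose 80.4-fold (from 4.18 ± 0.202 to 336 ± 17.8 CPM, log2 fold change 6.33 ± 0.15 SE, adjusted p = 6.44e-09) and 35.7-fold. Also armZ, whose product relieves repression of this pump, rose 57.4-fold. The largest rises by the naming rule were in kdpF, a potassium transporter gene with 8 counts over both control libraries, and in tauA for taurine uptake (4415796 to 4416809, minus strand, 214-fold, from 3.65 ± 0.0940 to 781 ± 62.5 CPM). Next came the RNA helicase gene deaD (3193886 to 3195589, minus strand, 141-fold, from 9.07 ± 0.535 to 1278 ± 33.2 CPM) and ssuA for sulfonate uptake (86.2-fold). The largest falls were in pqsB of quinolone signal synthesis (1080009 to 1080860, plus strand, 1309-fold, from 1498 ± 96.9 to 1.13 ± 0.431 CPM), pqsC (354-fold) and hcnB of hydrogen cyanide synthesis (226-fold). The chaperonin gene groEL (4915481 to 4917124, minus strand) fell 106-fold, from 13950 ± 442 to 132 ± 10.6 CPM.

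In all, 4422 of 5647 genes (78.3%) changed, 2188 higher and 2234 lower. At least 2-fold changes made up 1596 and 1622 of these. With library sizes only 245 genes were called, 24.1% of them higher (49.5% with TMM factors), and the median of all genes was -0.52. Sulfur assimilation and sulfonate use had 20 of 22 members higher and 1 lower (20 and 1 adjusted over the list alone) at a median log2 fold change of 3.70 (camera adjusted p = 7.56e-07, and adjusted p = 0.0521 with an estimated correlation). Type III secretion had 24 of 38 members higher and 6 lower (24 and 6 adjusted over the list alone) at a median of 0.93 (camera adjusted p = 0.00705, and adjusted p = 0.471 with an estimated correlation). The secretin gene pscC rose 8.95-fold.

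The other 8 lists that passed were lower with eravacycline. Later genes in runs of neighbouring genes were lower with eravacycline in general, as described at the end. The median log2 fold change was 0.33 at position 1 of a run and -1.75 at position 5 or later. Camera took no account of position, and how far it contributed to these list results was not tested. Denitrification and arginine fermentation had 24 of 25 members lower (24 adjusted over the list alone) at a median of -3.38 (camera adjusted p = 3.89e-08, and adjusted p = 0.0521 with an estimated correlation). Its nirS fell 61.2-fold, from 1458 ± 75.6 to 23.8 ± 1.13 CPM. Quorum sensing and secreted virulence factors had 24 of 26 lower and 1 higher (24 and 1 adjusted over the list alone) at a median of -4.71 (camera adjusted p = 3.89e-08, and adjusted p = 0.29 with an estimated correlation). Pyochelin had 14 of 14 lower (14 adjusted over the list alone) at a median of -4.12 (camera adjusted p = 1.02e-05, and adjusted p = 0.29 with an estimated correlation). Its pchA fell 65.3-fold. Heat shock had 13 of 15 lower and 1 higher (13 and 1 adjusted over the list alone) at a median of -3.07 (camera adjusted p = 9.53e-05, and adjusted p = 0.471 with an estimated correlation). The aerobic respiratory chain had 28 of 36 lower and 6 higher (28 and 6 adjusted over the list alone) at a median of -2.47 (camera adjusted p = 3.91e-05, and adjusted p = 0.471 with an estimated correlation). Here ccoO2 of a cbb3 oxidase fell 146-fold and nuoM of the NADH dehydrogenase 98.7-fold. The PmrAB/PhoPQ list had 14 of 15 lower (14 adjusted over the list alone) at a median of -2.40 (camera adjusted p = 3.91e-05, and adjusted p = 0.248 with an estimated correlation). Its oprH fell 18.4-fold. SOS response and pyocins had 29 of 39 lower and 8 higher (30 and 8 adjusted over the list alone) at a median of -1.85 (camera adjusted p = 0.00203, and adjusted p = 0.267 with an estimated correlation). The pyocin gene PA0634 fell 23.4-fold and recA rose 1.58-fold. H1 type VI secretion had 11 of 15 lower and 2 higher (11 and 2 adjusted over the list alone) at a median of -1.95 (camera adjusted p = 0.0122, and adjusted p = 0.248 with an estimated correlation). Its hcp1 fell 27.8-fold. Of the 15 lists that did not pass, ribosomal proteins had 15 of 53 higher and 17 lower (15 and 16 adjusted over the list alone, adjusted p = 0.732, 23 higher without BSS replicate 1), with a median of -0.15 and a mean of 0.17. Translation factors and ribosome assembly had 10 of 17 higher and 4 lower (10 and 4 adjusted over the list alone, adjusted p = 0.118). Its rimP rose 40.6-fold, and the list passed by fry (adjusted p = 0.000579, higher). Multidrug efflux had 17 of 32 higher and 11 lower (17 and 11 adjusted over the list alone, camera adjusted p = 0.277) at a median of 0.70. That list passed by fry too (adjusted p = 7.51e-05, higher). In this comparison fry passed 20 of the 25 lists, against 10 by camera. Eravacycline libraries held 55.8% ± 4.72 of counts on rRNA genes (SD, n = 2), against 8.62% ± 1.05 in control.

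The comparison of the combination with control gives the joint response. The gene tpbA rose 367-fold, from 1.27 ± 0.0230 to 468 ± 28.4 CPM (log2 fold change 8.52 ± 0.21 SE, adjusted p = 5.44e-09), and arsR 129-fold. The regulator gene iscR (PA3815, 4272165 to 4272656, minus strand) rose 31.0-fold, from 9.28 ± 0.530 to 288 ± 17.2 CPM, and the efflux gene muxA (PA2528, 2854011 to 2855291, minus strand) 38.0-fold, from 21.4 ± 2.11 to 814 ± 8.31 CPM. The efflux gene mexX rose 86.2-fold and armZ 74.2-fold. The largest falls included pqsB (1081-fold), pqsC (451-fold) and ccoO2 (302-fold). In all, 4459 genes (79.0%) changed, 2236 higher and 2223 lower. The change was at least 2-fold in 1621 and 1626 of them. With library sizes only the count was 291 (39.2% higher, against 50.2% with TMM factors) at a median of -0.12 for all genes.

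Against control, 11 lists passed in the combination. Here too, genes at position 1 of a run had a median log2 fold change of 0.33, against -1.87 at position 5 or later. The part of position in these list results was not tested. Iron-sulfur cluster assembly had 7 of 8 members higher (7 adjusted over the list alone) at a median of 1.72 (camera adjusted p = 0.0073, and adjusted p = 0.44 with an estimated correlation). Sulfur assimilation and sulfonate use had 21 of 22 higher and 1 lower (21 and 1 adjusted over the list alone) at a median of 3.96 (camera adjusted p = 4.45e-07, and adjusted p = 0.0488 with an estimated correlation). Type III secretion had 28 of 38 higher and 5 lower (28 and 5 adjusted over the list alone) at a median of 1.29 (camera adjusted p = 0.000645, and adjusted p = 0.389 with an estimated correlation). Denitrification and arginine fermentation had 25 of 25 lower (25 adjusted over the list alone) at a median of -4.44 (camera adjusted p = 1.29e-08, and adjusted p = 0.0488 with an estimated correlation). Pyochelin had 14 of 14 lower, median -4.15 (14 adjusted over the list alone, camera adjusted p = 1.19e-05, and adjusted p = 0.282 with an estimated correlation). Quorum sensing had 24 of 26 lower and 1 higher, median -4.92 (24 and 1 adjusted over the list alone, camera adjusted p = 2.65e-08, and adjusted p = 0.282 with an estimated correlation). The PmrAB/PhoPQ list had 14 of 15 lower, median -1.56 (14 adjusted over the list alone, camera adjusted p = 0.000506, and adjusted p = 0.27 with an estimated correlation). Heat shock had 13 of 15 lower and 1 higher, median -2.68 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000136, and adjusted p = 0.44 with an estimated correlation). The aerobic respiratory chain had 26 of 36 lower and 6 higher, median -2.49 (26 and 6 adjusted over the list alone, camera adjusted p = 0.000136, and adjusted p = 0.44 with an estimated correlation). H1 type VI secretion had 11 of 15 lower and 2 higher, median -2.25 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0112, and adjusted p = 0.27 with an estimated correlation). SOS response and pyocins had 28 of 39 lower and 7 higher, median -1.59 (29 and 7 adjusted over the list alone, camera adjusted p = 0.00158, and adjusted p = 0.27 with an estimated correlation). Type III secretion had 3 lower without combination replicate 2.

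The comparison of the combination with eravacycline asks what BSS added when the antibiotic was present. The gene tpbA rose 156-fold, from 2.99 ± 0.00944 to 468 ± 28.4 CPM (n = 2 per group, log2 fold change 7.29 ± 0.20 SE, adjusted p = 1.21e-07). All 8 members of iron-sulfur cluster assembly rose (8 adjusted over the list alone), at a median of 2.02 (camera adjusted p = 6.66e-18, and adjusted p = 0.111 with an estimated correlation). The scaffold gene iscU (4270499 to 4270885, minus strand) rose 5.26-fold (from 54.2 ± 0.704 to 285 ± 26.0 CPM) and iscR 4.09-fold (from 70.3 ± 4.52 to 288 ± 17.2 CPM). The diacylglycerol kinase gene dgkA rose 6.30-fold, the efflux genes muxA 6.17-fold (from 132 ± 7.93 to 814 ± 8.31 CPM) and muxB 5.19-fold, and the cytochrome c peroxidase gene ccpR 5.50-fold. The largest falls by the naming rule were in hemN, for heme synthesis without oxygen (1682567 to 1683949, minus strand, 6.48-fold, from 118 ± 9.72 to 18.2 ± 0.136 CPM), and in the denitrification regulator gene dnr (log2 fold change -2.32). They were followed by narK1 (4.77-fold), arcD of arginine fermentation (3.33-fold), the acetate kinase gene ackA (3.10-fold) and the porin gene oprG (3.09-fold).

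Altogether 270 of 5647 genes (4.78%) changed, 152 higher and 118 lower. The change was at least 2-fold in 93 and 51, and 858 genes had an unadjusted p under 0.05. The count was 164 and 165 without eravacycline replicates 1 and 2, 151 and 154 without combination replicates 1 and 2, 659 without either BSS replicate and 1138 in the fit of these 2 groups alone. With library sizes only it was 2 (43 at an unadjusted p under 0.05) at a median of 0.38 for all genes. The combination libraries held 39.0% ± 19.4 of counts on rRNA genes (SD, n = 2), and eravacycline libraries 55.8% ± 4.72. The fit took the spread of a gene from all 8 libraries. Replicates differed most with BSS, where log2 ratios of protein-coding genes had an SD of 0.458. That SD was 0.206 with eravacycline and 0.194 with the combination. The counts of 270 here and 1507 for BSS against control therefore do not rank the 2 BSS effects. In fits of only the groups compared they were 1138 and 868.

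Multidrug efflux had 9 of 32 members higher (13 higher and 1 lower adjusted over the list alone) at a median of 0.28 (camera adjusted p = 1.16e-05, and adjusted p = 0.194 with an estimated correlation). Its muxC rose 2.26-fold and mexE 2.04-fold. The higher count was 5 without either combination replicate. The efflux gene mexX had a log2 fold change of 0.10 (adjusted p = 0.803). The PmrAB/PhoPQ list had 6 of 15 higher (8 adjusted over the list alone) at a median of 0.68 (camera adjusted p = 1.19e-07, and adjusted p = 0.111 with an estimated correlation). Its PA4773 rose 2.59-fold and PA4774 2.41-fold, with 2 members higher without eravacycline replicate 1 or combination replicate 1. Type III secretion had 5 of 38 higher (17 adjusted over the list alone) at a median of 0.45 (camera adjusted p = 2.81e-09, and adjusted p = 0.147 with an estimated correlation). There were 0 higher in edgeR without eravacycline replicate 1 or either combination replicate and 20 without either BSS replicate. Sulfur assimilation and sulfonate use had 0 of 22 called by edgeR (2 higher adjusted over the list alone, 7 at an unadjusted p under 0.05, 1 by DESeq2) at a median of 0.23 (camera adjusted p = 0.00171, and adjusted p = 0.111 with an estimated correlation), and 6 were higher without either BSS replicate. Copper, zinc and cadmium efflux had 1 of 13 higher, PA3690 (4.64-fold, from 19.4 ± 1.16 to 89.9 ± 3.58 CPM, 1 adjusted over the list alone), at a median of 0.23 (camera adjusted p = 0.0129, and adjusted p = 0.262 with an estimated correlation). That list did not pass without eravacycline replicate 1 (adjusted p = 0.122, range 0.00319 to 0.122 over 10 alternatives).

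Denitrification and arginine fermentation had 7 of 25 members lower in the combination than with eravacycline (8 adjusted over the list alone, camera adjusted p = 5.85e-05, and adjusted p = 0.111 with an estimated correlation), at a median of -0.33 that was 0.04 with library sizes only, against 0.38 for all genes. Quorum sensing and secreted virulence factors had 0 of 26 called by edgeR (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.0178, and adjusted p = 0.608 with an estimated correlation), at a median of -0.22 that was 0.18 with library sizes only. Without BSS replicate 2, 5 were lower. Its adjusted p was 0.0661 without eravacycline replicate 1 (range 0.0127 to 0.0661 over 10 alternatives). Flagella and chemotaxis had 1 of 43 lower, flgK (1.33-fold, adjusted p = 0.0489), which did not pass when adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.565 with an estimated correlation), at a median of -0.10 that was 0.28 with library sizes only. That list did not pass without eravacycline replicate 1 (adjusted p = 0.229) or combination replicate 1 (0.0595, range 0.00361 to 0.229 over 10 alternatives). By fry neither quorum sensing (adjusted p = 0.353) nor flagella (0.145) passed.

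Of the 16 lists that did not pass, 4 did so with a library left out. The aerobic respiratory chain had 3 of 36 members higher and 8 lower (6 and 9 adjusted over the list alone, adjusted p = 0.0617), at a median of -0.19 that was 0.19 with library sizes only. It passed without eravacycline replicate 2 (0.00798) and combination replicate 1 (0.0186, range 0.00798 to 0.242 over 10 alternatives). The lower count was 2 without either combination replicate, and the higher count 1 without eravacycline replicate 1. The Pf1 prophage (adjusted p = 0.0549, median -0.26, or 0.11 with library sizes only) passed without either control replicate, either BSS replicate or combination replicate 1, over a range of 0.0134 to 0.193. ATP synthase (adjusted p = 0.0667, median 0.26) passed without BSS replicate 1 (0.00903) or 2 (0.0089, range 0.0089 to 0.186). The list of other iron uptake and Fur-repressed genes had 3 of 22 higher (4 adjusted over the list alone, adjusted p = 0.0693), among them PA5217 (1.99-fold) and feoB (1.77-fold). It passed without combination replicate 2 (0.0409, range 0.0409 to 0.223), with 6 higher without either BSS replicate. Ribosomal proteins had a median of 0.09 (adjusted p = 0.292), and 0 of 53 were called by edgeR or DESeq2 or at an unadjusted p under 0.05.

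The comparison of the combination with BSS asks what eravacycline added. The largest rises by the naming rule were in tauA (231-fold, from 4.21 ± 0.400 to 973 ± 22.1 CPM), ssuA (149-fold), deaD (145-fold) and the sulfate binding gene sbp (121-fold, from a mean of 11.7 to 1412 CPM). The largest falls included pqsB (352-fold), arcB of arginine fermentation (153-fold, from 2070 ± 164 to 13.5 ± 0.932 CPM), the enoyl reductase gene fabI (151-fold) and nuoM (136-fold). In all, 4464 genes (79.1%) changed, 2242 higher and 2222 lower, and 1585 and 1665 of them by at least 2-fold. With library sizes only the count was 264 (59.9% higher, against 50.2% with TMM factors), at a median of 0.34 for all genes. Camera, which took no account of a gene's position in runs of neighbouring genes, passed 14 lists. Those of sulfur assimilation and sulfonate use (21 of 22 higher and 1 lower, 21 and 1 adjusted over the list alone, median 4.24, camera adjusted p = 1.64e-07) and denitrification and arginine fermentation (25 of 25 lower, 25 adjusted over the list alone, median -3.56, camera adjusted p = 2.6e-08) passed with an estimated correlation too (adjusted p = 0.0415 for both). Ribosomal proteins had 40 of 53 members higher and 3 lower (40 and 3 adjusted over the list alone) at a median of 1.31 (camera adjusted p = 1.86e-05, and adjusted p = 0.45 with an estimated correlation). There were 7 lower without BSS replicate 2, the library with 92.5% of counts on rRNA. Iron-sulfur cluster assembly had 6 of 8 higher (6 adjusted over the list alone) at a median of 1.21 (camera adjusted p = 0.0187, and adjusted p = 0.45 with an estimated correlation). It did not pass without BSS replicate 2 (adjusted p = 0.0548, range 0.00617 to 0.0548 over 10 alternatives). Type III secretion had 31 of 38 higher and 3 lower, median 2.02 (31 and 3 adjusted over the list alone, camera adjusted p = 3.09e-06, and adjusted p = 0.249 with an estimated correlation). The PmrAB/PhoPQ list had 15 of 15 lower, median -3.30 (15 adjusted over the list alone, camera adjusted p = 7.99e-06, and adjusted p = 0.174 with an estimated correlation). Translation factors and ribosome assembly had 12 of 17 higher and 1 lower, median 2.06 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00299, and adjusted p = 0.45 with an estimated correlation). Flagella and chemotaxis had 27 of 43 higher and 10 lower, median 0.66 (27 and 10 adjusted over the list alone, camera adjusted p = 0.0305, and adjusted p = 0.45 with an estimated correlation). Quorum sensing had 24 of 26 lower and 2 higher, median -4.08 (24 and 2 adjusted over the list alone, camera adjusted p = 1.81e-07, and adjusted p = 0.326 with an estimated correlation). Pyochelin had 13 of 14 lower, median -2.89 (13 adjusted over the list alone, camera adjusted p = 9.87e-05, and adjusted p = 0.326 with an estimated correlation). The aerobic respiratory chain had 30 of 36 lower and 4 higher, median -2.77 (30 and 4 adjusted over the list alone, camera adjusted p = 3.01e-06, and adjusted p = 0.333 with an estimated correlation). Heat shock had 13 of 15 lower and 1 higher, median -2.02 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000355, and adjusted p = 0.45 with an estimated correlation). H1 type VI secretion had 11 of 15 lower and 2 higher, median -2.30 (11 and 2 adjusted over the list alone, camera adjusted p = 0.00324, and adjusted p = 0.174 with an estimated correlation). SOS response and pyocins had 30 of 39 lower and 8 higher, median -1.83 (30 and 8 adjusted over the list alone, camera adjusted p = 0.00148, and adjusted p = 0.249 with an estimated correlation). Without combination replicates 1 and 2 the lower flagella count was 6 and 5.

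The interaction asks whether BSS changed genes by the same factor with and without eravacycline. It differed for 857 genes (15.2%), more positive with eravacycline in 522 and more negative in 335, and by at least 2-fold in 282 and 192. The rise in arsC with BSS was 27.8-fold smaller with eravacycline than without it (interaction -4.80 ± 0.16 SE, log2, adjusted p = 8.28e-07), and the interaction was -4.68 for inaA, -3.71 for arsR and -3.68 for arsB. These folds started from a level that eravacycline alone had raised 66.1-fold for arsR, 14.8-fold for arsB, 3.14-fold for arsC and 13.5-fold for inaA, the last 3 values chosen after they were seen. It was 3.02 for mexJ, 2.98 for fpvA, 2.89 for ccpR and 2.72 for fpr, a ferredoxin reductase gene. The efflux gene mexX (-1.01) and mexY (-1.51) differed too. The count was 547 and 473 without control replicates 1 and 2, 1982 without BSS replicate 1, 1236 without BSS replicate 2, 411 and 426 without eravacycline replicates 1 and 2, and 430 and 400 without combination replicates 1 and 2. With library sizes only edgeR called 0 genes (28 at an unadjusted p under 0.05, against 694 by DESeq2 with its own size factors) at a median of 0.87 for all genes.

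Eravacycline alone had already lowered the pyochelin, quorum sensing and heat shock lists (median log2 fold changes -4.12, -4.71 and -3.07 against control). It had raised type III secretion (0.93) and sulfur assimilation (3.70). Whether low starting levels limited a further fall with BSS was not tested. By list, the BSS effect was more positive with eravacycline for ribosomal proteins, in 33 of 53 members (44 adjusted over the list alone) at a median of 1.22 (camera adjusted p = 5.03e-17, and adjusted p = 0.24 with an estimated correlation). Its count was 11 without eravacycline replicate 2 and 50 without BSS replicate 2. Type III secretion had 27 of 38 members more positive (30 adjusted over the list alone) at a median of 1.16 (camera adjusted p = 1.54e-14, and adjusted p = 0.148 with an estimated correlation), or 14 without eravacycline replicate 1. Iron-sulfur cluster assembly had 8 of 8 (8 adjusted over the list alone) at a median of 1.55 (camera adjusted p = 2.01e-07, and adjusted p = 0.202 with an estimated correlation). Pyochelin had 8 of 14 (12 adjusted over the list alone) at a median of 1.12 (camera adjusted p = 4.63e-07, and adjusted p = 0.202 with an estimated correlation). Sulfur assimilation and sulfonate use had 11 of 22 (12 adjusted over the list alone) at a median of 0.66 (camera adjusted p = 1e-05, and adjusted p = 0.148 with an estimated correlation), or 7 without eravacycline replicate 2. ATP synthase had 7 of 9 (8 adjusted over the list alone) at a median of 1.40 (camera adjusted p = 2.43e-05, and adjusted p = 0.148 with an estimated correlation), or 3 without control replicate 2. Translation factors and ribosome assembly had 5 of 17 (8 adjusted over the list alone) at a median of 0.82 (camera adjusted p = 5.1e-05, and adjusted p = 0.365 with an estimated correlation), or 12 without BSS replicate 1 and 0 without control replicate 2. Quorum sensing and secreted virulence factors had 10 of 26 and 1 more negative (11 and 1 adjusted over the list alone) at a median of 0.50 (camera adjusted p = 0.000839, and adjusted p = 0.365 with an estimated correlation). Heat shock had 5 of 15 (7 adjusted over the list alone, camera adjusted p = 0.000831, and adjusted p = 0.386 with an estimated correlation), or 1 without combination replicate 1 and 11 without BSS replicate 1, and did not pass by fry (adjusted p = 0.0761). The list of other iron uptake and Fur-repressed genes had 5 of 22 (5 adjusted over the list alone, camera adjusted p = 0.00535, and adjusted p = 0.202 with an estimated correlation), a count of 3 to 9 over the libraries left out. It did not pass without BSS replicate 1 (adjusted p = 0.103, range 0.000656 to 0.103 over 10 alternatives). Pyoverdine did not pass (adjusted p = 0.0603, 3 of 19 more positive, 4 adjusted over the list alone), but did so without control replicate 1 (0.0244), eravacycline replicate 2 (0.045) or combination replicate 2 (0.0455, range 0.0244 to 0.209 over 10 alternatives). Without BSS replicate 1, 6 of its members were more positive. The PmrAB/PhoPQ list was more negative in 7 of 15 members and more positive in 2 (8 and 3 adjusted over the list alone, camera adjusted p = 0.000831, and adjusted p = 0.202 with an estimated correlation), at a median of -0.86 that was 0.22 with library sizes only, against 0.87 for all genes. There were 4 more negative without either control replicate. Alginate passed (camera adjusted p = 0.0123, and adjusted p = 0.202 with an estimated correlation) with 0 of 12 members called by edgeR (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2), at a median of -0.39 that was 0.53 with library sizes only. Alginate did not pass without control replicate 1 (adjusted p = 0.0617) or BSS replicate 1 (0.0572, range 0.0041 to 0.0617 over 10 alternatives).

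Over the comparisons in the order above, fry passed 20, 20, 20, 10, 24 and 13 lists, among them 15 of the 15, 10 of the 10, 11 of the 11, 7 of the 9, 14 of the 14 and 11 of the 12 that passed camera with the preset correlation.

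The BSS effects without and with eravacycline rest on separate libraries and were compared directly. Their calls are not fully separate, since both used a spread per gene estimated from all 8 libraries. The expected numbers and Fisher's exact tests below do not allow for this. Of the 152 genes higher in the combination than with eravacycline, 79 (52.0%) were also higher with BSS than in control, against 17.5 expected if the calls were independent (Fisher's exact test, p = 9.51e-36, which treats genes as independent). Another 22 were lower with BSS, against 23.1 expected. Of the 118 lower genes, 42 (35.6%) were also lower with BSS alone, against 17.9 expected (Fisher's exact test, p = 2.66e-08), and 6 were higher, against 13.6 expected. Across the 5647 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.25 (Spearman's rho 0.12).

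**Figure D3:**
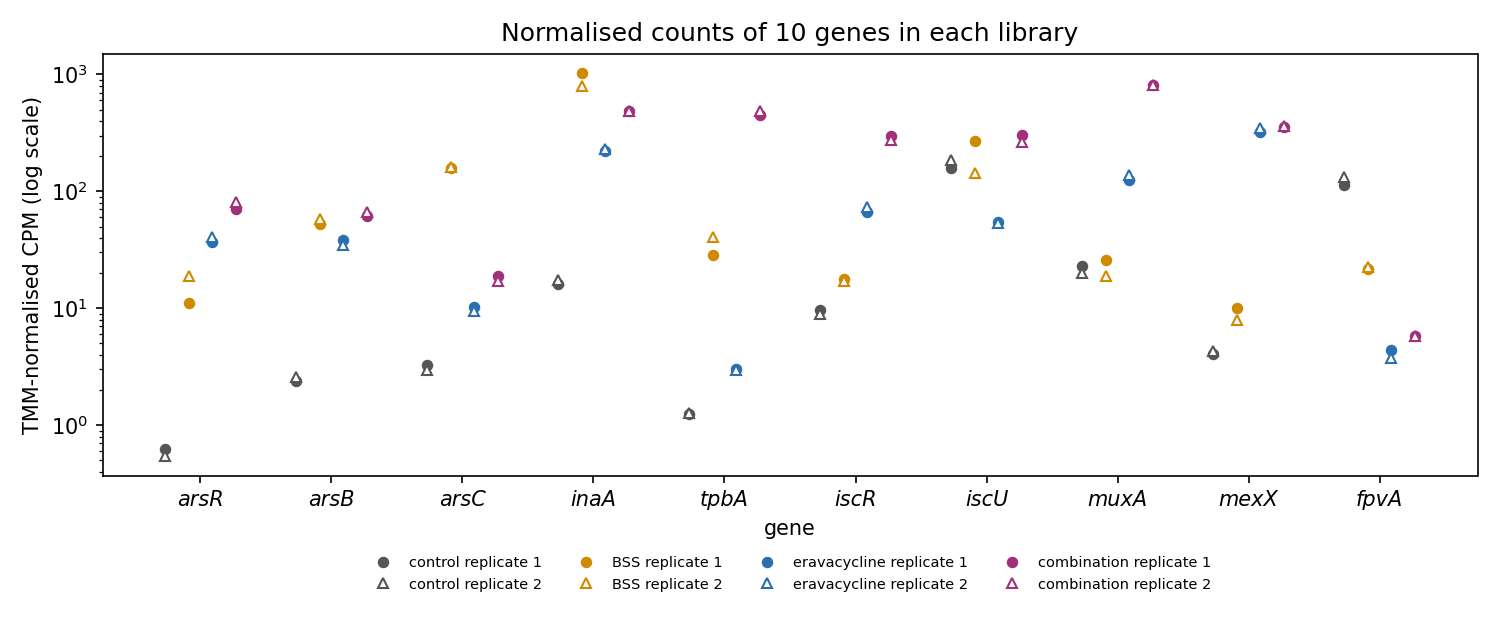
Points give TMM-normalised counts per M on a log axis for 10 genes in each of the 8 libraries, with circles for replicate 1 and triangles for replicate 2. The level of arsC was 3.13 CPM in control and 160 CPM with BSS, and that of tpbA was 2.99 CPM with eravacycline and 468 CPM with the combination.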

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

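The 4 tests of a ceiling on the arsenic resistance genes and inaA, and the comparison of these genes with control under eravacycline, were chosen only after the results were seen. The effect of BSS differed with and without eravacycline, by the test of the interaction, for 857 genes. The named genes with the largest differences between the 2 BSS effects were mexJ (3.02), fpvA (2.98), ccpR (2.89), fpr (2.72), arsC (-4.80), inaA (-4.68), arsR (-3.71) and arsB (-3.68), all on the log2 scale. No group held more than 2 libraries, so no library was tested as lying far from the others of its group.

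The arsenic resistance genes and inaA rose by a smaller factor with BSS in the presence of eravacycline, from a level that eravacycline alone had already raised (log2 fold change against control 6.05 for arsR, 3.88 for arsB, 1.65 for arsC and 3.76 for inaA). The high rRNA share of BSS replicate 2 is argued against as the cause, since the median interaction of the 4 genes was -4.21 without that library. The level of arsR with BSS alone was not its maximum, since it was higher in the combination (log2 fold change 2.34 against BSS). Eravacycline alone had already raised arsR above that level, so the outcome of this test was settled in advance. A ceiling at a higher level was not tested for arsR. For arsB (0.21), arsC (-3.15) and inaA (-0.92) a ceiling cannot be told apart from other explanations, since they stand at positions 2, 3 and 2 of runs of neighbouring genes, and later genes of runs were lower with eravacycline in general. How both drugs act on these genes together, the biological side that the design gives, stays open, since the interaction shows a difference and not its mechanism.

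Ribosomal protein genes were lower with BSS alone, and BSS replicate 2 had 92.5% of its counts on rRNA genes. Without that library the list median was -0.88, and in the 2 BSS libraries taken singly 53 of 53 members (replicate 1, median -0.88) and 49 of 53 (replicate 2, median -1.64) lay below the control mean, so that library alone did not set the pattern. The list median of -1.16 lay below all of 10000 random lists matched for coding length and abundance (median -0.36, lowest -0.73). As far as this matching reaches, a trend with both is argued against as the whole cause. How close the matched genes were was not checked. The random lists drew genes singly, whereas members moved together (estimated correlation 0.42), so the range of the random lists can be too narrow. What stays open is a response to BSS, such as slower growth, and a difference in the state of the cultures at sampling, neither of which was tested.

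The 8 genes of the iron-sulfur cluster list, which lie next to one another, were higher in the combination than with eravacycline. Combination replicate 2 had a lower rRNA share (25.3%) than replicate 1 (52.7%), but the list median was 2.11 without it, so it did not set the pattern. The median of 2.02 lay above all of 10000 random lists of singly drawn genes matched for length and abundance (highest 0.76). As adjacent genes of probably few transcripts, the 8 members do not make 8 independent findings. With BSS alone, 4 of the 8 were higher than control too (list median 0.44), so a smaller rise was seen without eravacycline. The interaction median was 1.55. With eravacycline alone, 1 was higher and 4 were lower than control (median -0.25, camera adjusted p = 0.728). A demand for new iron-sulfur clusters when both drugs are present stays open as a hypothesis, and no test of it was possible in these data.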

How the results depend on the processing

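The setting with rRNA and tRNA genes removed and BSS replicate 2 left out was chosen only after the data were seen. Of the 561 named gene results, 360 lost their call and 4 changed direction when library sizes replaced TMM factors. Over the left-out libraries, 4246 of these named gene values kept direction and call, 210 lost the call and 31 gained it. Of the list results, 1167 kept both, 14 lost the call and 19 gained it. The counts of changed genes with library sizes only were 0 for BSS against control (1507 with TMM factors), 245 for eravacycline against control (4422), 291 for the combination against control (4459), 2 against eravacycline (270), 264 against BSS (4464) and 0 for the interaction (857). The named genes that changed direction had log2 fold changes of -0.10 (tssA1), -0.20 (znuA) and -0.0640 (PA0722) with BSS and an interaction of 0.11 (katA), where the medians of all genes had moved to -0.50 and 0.87. Among all called genes, the sign with library sizes only differed for 124 of 1507 with BSS and 126 of 4422 with eravacycline. It differed for 37 of 4464 in the combination against BSS and 116 of 857 for the interaction. For the combination against control and against eravacycline the number was 0. In fits of only the groups compared, the count was 868 for BSS against control and 1138 for the combination against eravacycline. The setting chosen later gave 744 genes for the combination against eravacycline and 1360 for the interaction. With 1 library left out in turn, the counts ranged from 843 to 2501 for BSS against control, from 151 to 659 for the combination against eravacycline and from 400 to 1982 for the interaction. Over the 6 comparisons 71 list results passed, against 4 with an estimated correlation between genes. The cause of these differences was not tested. With library sizes only, the combination against control kept 291 of 4459 calls, though the median of all genes was -0.12. TMM factors also scaled the replicates of a group to each other. Totals of BSS replicates 1 and 2 were 13.25 M and 30.68 M, against effective sizes of 24.45 M and 5.12 M with TMM factors. Estimated correlations between genes ranged from -0.07 (oxidative stress) to 0.57 (heat shock) over the lists, against the preset 0.01. All other alternatives left each count of changed genes within 1.5 times its value. BSS replicate 2 had the fewest protein-coding counts, 2.20 M. The simulation, which gave each gene 1 spread in all groups, recovered 78% of genes changed 2-fold for BSS against control. It recovered 72% for the combination against eravacycline.

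With the replicate number as a block, the counts were 1336 for BSS against control, 4373 for eravacycline against control, 4409 for the combination against control, 232 against eravacycline, 4419 against BSS and 711 for the interaction, and 73 list results passed. The 2 lists added were the Pf1 prophage and the aerobic respiratory chain in the combination against eravacycline (adjusted p = 0.0479 for both). Libraries with the same number did not deviate together, with correlations of their deviations from the group means of -0.161 to -0.0155 over the 6 pairs of groups, so the numbers were not treated as a pairing.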

Other observations

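The tests on runs of neighbouring genes below were chosen only after the falls along the arsenic resistance and iron-sulfur genes had been seen, and the 4 genes of the next paragraph after their values were seen.

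The genes with no symbol held some of the largest effects of BSS in the presence of eravacycline. PA4517 (5057716 to 5059518, plus strand) was 328-fold higher in the combination than with eravacycline, from 2.53 ± 0.870 to 831 ± 24.4 CPM (n = 2 per group, log2 fold change 8.36 ± 0.26 SE, adjusted p = 2.19e-07). PA3206, the sensor gene of a regulator pair of the envelope stress type (3595942 to 3597279, plus strand), rose 77.9-fold, from 3.77 ± 0.176 to 294 ± 5.36 CPM, and its neighbour PA3205 (3595387 to 3595827) rose 60.5-fold, from 18.0 ± 1.51 to 1091 ± 106 CPM. PA3886, next to tpbA on the same strand, rose too (log2 fold change 5.64 ± 0.16 SE).

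A hypothesis was that RNA is lost towards the end of transcription units in cells given eravacycline. Among 425 runs of at least 3 protein-coding genes on the same strand with gaps of at most 50 bases, the last gene had a lower log2 fold change than the first in 335 runs (78.8%) with eravacycline against control, at a median difference of -1.22 (permutation test with 10000 sign flips, p = 1e-04, the smallest it can give). In the combination against control it was lower in 333 runs (78.4%), at a median of -1.36 (sign-flip permutation test, p = 1e-04). BSS against control showed no such loss, with 188 runs (44.2%) and a median of 0.0798 (sign-flip permutation test, p = 0.01). These tests treat runs as replicates, though every run comes from the same 2 libraries per group. Their p-values, and the SE of the regression below, therefore do not measure spread between cultures. The median log2 fold change with eravacycline was 0.33 at position 1 of a run, -0.37 at position 2, -0.82 at position 3, -1.27 at position 4 and -1.75 at position 5 or later. It was 0.29 for genes standing alone, with no same-strand neighbour within 50 bases. Genes in runs of 2 were in neither group. A linear trend with coding length and abundance is argued against as the whole cause. In a regression on the differences in both, the difference between last and first gene was -1.30 ± 0.08 SE at no difference in either. Abundance was taken from the BSS libraries, and its own term was -0.53 ± 0.05 SE. Other forms of the trend were not tested. The hypothesis remains open and was found and tested on the same data. Runs are a stand-in for transcription units, which were not mapped here, and the large falls in late genes of operons such as nuo may hold a part of this loss. In pqsABCDE, however, pqsB fell further than the later pqsC, both with eravacycline and in the combination.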
